A study of Mus musculus with 6 samples.

How the data were processed

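The data were RNA-seq libraries from cold-stimulated inguinal white adipose tissue of WT and Rarres2-/- C57BL/6 mice, 3 of each. Per the labels, total RNA was extracted with a lipid tissue kit, Illumina libraries were prepared, and 8-week-old mice were used. The temperature and duration of the cold are not given in the sources used here, nor are the deleted part of Rarres2 or the sex of the mice. Values were deposited by the authors as FPKM (fragments scaled to transcript length and to the total of mapped fragments), 1 table per library, per the file headers. The table of WT replicate 3 names the sample in place of a unit. Its gene rows, decimals and scale were those of the other 5 tables (median FPKM of tested genes 9.23, others 9.05 to 9.37), and it was read as FPKM. The submitters' processing notes name Bowtie and mm10. The program that computed FPKM, the annotation, its handling of reads shared between gene copies, strand and all versions are not given in the sources used here. FPKM divides by transcript length and library total, so it removes depth, and a shift in a few very abundant genes can move all others.

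The tables held 17342 named genes and 737 rows without a symbol. The unnamed rows made up 0.793% to 4.91% of the summed values and stayed out of the tests. Of the named genes, 405 were at 0 in all libraries. No pair of libraries held equal values for any gene above 0 in both. Summed FPKM of named genes ran from 500311 to 809109 in 5 libraries and was 1.88e+06 in WT replicate 1, where the small nucleolar RNA gene Snord2 alone held 62.1% of the sum. Without 40 genes of small RNAs the sums were 453919 to 678129. FPKM holds no counts, so the absolute depth is unknown and counting intervals cannot be given. Ratios of values below 0.15 FPKM between libraries cluster at the ratio of what a read is worth. That gave depths relative to WT replicate 2 of 0.497 for WT replicate 1, 1.01 for WT replicate 3, and 1.00, 0.747 and 0.697 for Rarres2-/- replicates 4, 5 and 6.

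Genes with a mean of at least 1 FPKM over all libraries (11086) were tested on log2(FPKM + 1), a scale that understates the change of low genes, with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided). The contrast was Rarres2-/- minus WT, with genotype as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. All adjusted p-values are from limma, per gene or by its camera or fry functions per list. The design fixed beforehand allowed for counts or normalized values, and the branch for normalized values was used. Sample numbers are not shared between genotypes, so no block was fitted. Single values were compared by exact permutation tests, for which the smallest p with 3 against 3 libraries is 0.1.

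Before the data were examined, 41 gene lists were fixed for thermogenesis, lipid and energy metabolism, immune signalling, stress, matrix, innervation, the clock and the cell cycle, and for cell types that the depot could hold. Of their members, 8 were matched by an older symbol and 31 had no row. Lists with at least 5 tested members (32) were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation and with fry. The 9 lists with fewer were not tested. Some genes stand in more than 1 list. Cd209a, for example, is in the dendritic cell and the alternatively activated macrophage list.

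Genes named in the text follow a rule fixed beforehand. It takes the 4 chemerin genes, up to 4 members with the smallest p from each list, sex-linked genes, and the genes past the threshold with separated groups. As fewer than 5 passed in either direction, the 10 with the smallest p in each direction were taken, with separated groups, a mean of at least 1 FPKM and no predicted-model symbol. Some genes that the rule takes are not reported here. Coordinates are those of RefSeq on GRCm38, the assembly that mm10 stands for. Transcript length and GC content came from the longest GENCODE M21 transcript of each symbol, found for 94.6% of tested genes.

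Alternatives were quantile normalization, upper-quartile scaling, scaling without the 20 most abundant genes, no filter, a filter of 5 FPKM in 3 libraries, array weights, no trend, a pseudocount of 0.1, robust empirical Bayes, an adjusted p of 0.1, an absolute log2 difference of at least 1, and each library left out in turn. For sample similarity, the 500 most variable genes were used. The scripts were tested on simulated values with the means and spreads of the 11086 genes of this comparison, in which 200 genes were changed. They recovered 33% of genes changed by a log2 difference of 1 and 76% of those changed by 2, and called 10 unchanged genes. Of simulated lists of 20 genes, 5 of 5 shifted by 0.5 and 0 of 27 unshifted were called. The simulated genes varied independently of each other, and no simulated library stood apart from its group. In the real lists the estimated correlation reached 0.907 (oxidative phosphorylation). The share of false list calls in the real data therefore cannot be read from the simulation. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.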

Results

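RNA was sequenced from inguinal white adipose tissue, a subcutaneous fat depot that forms heat-producing beige adipocytes in the cold, of 8-week-old C57BL/6 mice after cold stimulation. Wild-type (WT) mice were compared with Rarres2-/- mice, in which the gene for chemerin, a protein secreted by adipocytes, is disrupted. Each genotype had 3 libraries, numbered 1 to 3 in WT and 4 to 6 in Rarres2-/-. The comparison asks how loss of chemerin changes gene expression in cold-stimulated fat. No unstimulated fat was analysed here. The labels do not say that each library came from a separate mouse, and if it did not, the p-values measure only the spread between libraries. Expression was given as FPKM for 17342 named genes, of which 11086 had a mean of at least 1 FPKM and were tested. The absolute depth is unknown. The spacing of the lowest values put the depth of WT replicate 1 at 0.497 times that of WT replicate 2, and the other libraries between 0.697 and 1.01 times. All 6 libraries held the Y-linked gene Ddx3y at 33.8 to 55.2 FPKM and Xist at no more than 0.00992 FPKM.

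Rarres2 (chromosome 6, 48569696 to 48572845, GRCm38) was at 0.260, 6.35 and 1.41 FPKM in the Rarres2-/- libraries, against 436, 610 and 505 FPKM in WT. The mean was 517 ± 87.5 FPKM in WT and 2.67 ± 3.23 FPKM in Rarres2-/- (SD, n = 3 each), 193 times higher in WT. Its log2 difference was -7.51 (SE 0.592), lower in all 3 Rarres2-/- libraries, with an adjusted p of 0.0597 by limma, just outside the threshold of 0.05. That adjusted p was 0.00520 without Rarres2-/- replicate 5, the library with the highest residual value, and ran from 0.00198 to 0.469 over the alternatives. Which part of the gene is deleted is not given in the sources used here. Cmklr1, the signalling receptor of chemerin, was at 46.7 ± 12.6 FPKM in WT and 79.0 ± 18.2 FPKM in Rarres2-/-, higher in all 3 Rarres2-/- libraries than in any WT library, with a log2 difference of 0.75 (SE 0.249) and an adjusted p of 0.999. The other chemerin-binding receptors were low. Gpr1 was at 5.89 ± 4.33 FPKM in WT and 4.60 ± 2.02 FPKM in Rarres2-/-, with a log2 difference of -0.07 (SE 0.631) that changes sign when WT replicate 2 (0.23), WT replicate 3 (0.38) or Rarres2-/- replicate 4 (0.25) is left out. Ccrl2 was at 0.907 ± 0.457 and 1.10 ± 0.439 FPKM, with a log2 difference of 0.15 (SE 0.258) that is -0.06 without WT replicate 3 and -0.01 without Rarres2-/- replicate 4.

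**Figure D1:**
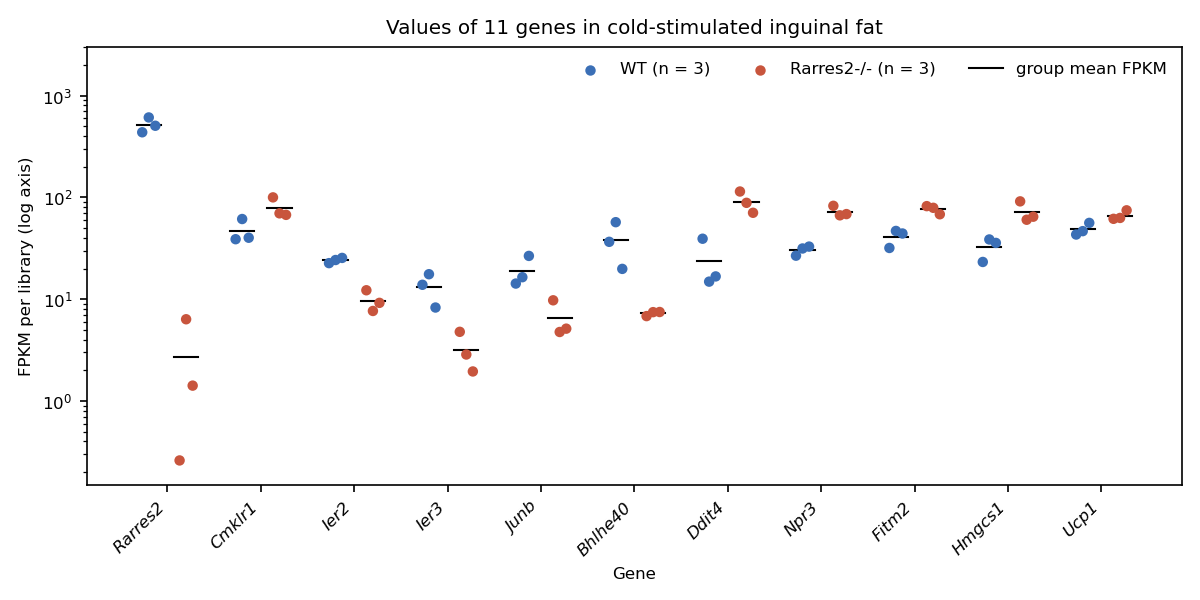
FPKM of 11 genes in each library, on a log axis, with 3 WT libraries (blue), 3 Rarres2-/- libraries (red) and the mean FPKM of each group (black lines). Rarres2 lies between 436 and 610 FPKM in WT and at 6.35 FPKM or below in Rarres2-/-. The 2 groups do not overlap in the genes shown, most of which were chosen by a rule that requires this. Named genes with overlapping libraries, such as Egr1, are not shown. Over all tested genes the groups did not overlap in 10.3%, where chance gives 10%.

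The genes with the smallest p among those higher in Rarres2-/- included Npr3, the clearance receptor for natriuretic peptides. It was at 30.3 ± 3.20 and 72.6 ± 8.75 FPKM (SD, n = 3 each), a log2 difference of 1.23 (SE 0.163). Ddit4, an inhibitor of mTORC1 signalling, had a log2 difference of 2.01 (SE 0.380), Arrdc3 1.70, Cxcr4 1.39, Irs2 1.10 and Tsc22d3 1.08. Myh1 (1.58), Fitm2 (0.90) and Paqr9 (0.78) were also among them. Among genes lower in Rarres2-/-, Bhlhe40, a transcriptional repressor of the clock, was at 19.8 to 57.1 FPKM in WT and 6.82 to 7.48 FPKM in Rarres2-/-, a log2 difference of -2.11 (SE 0.350). Ier3 had a log2 difference of -1.76, Klf10 -1.29, Ier2 -1.25, Id3 -1.13, Sertad3 -1.12, Dusp7 -1.09, Sertad1 -1.04, Ier5 -0.97 and St8sia4 -0.65. Each of these genes had all 3 Rarres2-/- libraries on the same side of all 3 WT libraries, which defined their selection.

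None of them passed the test. By limma, 0 of 11086 genes had an adjusted p under 0.05, the smallest after Rarres2 being 0.519. At an unadjusted p under 0.05 there were 436 genes, 244 higher and 192 lower in Rarres2-/-, where chance gives 554.3. The groups did not overlap in 1146 genes (10.3%, chance 10%), 644 higher and 502 lower. The count was also 0 without WT replicate 1 or without Rarres2-/- replicate 4. With array weights, which gave WT replicate 1 and Rarres2-/- replicate 4 weights of 0.192 and 0.179 and Rarres2-/- replicate 5 a weight of 6.19, limma called 1524 genes, 770 higher and 754 lower. Rarres2-/- replicate 6 had a weight of 0.736, so the Rarres2-/- side of that fit rests mainly on replicate 5. Without WT replicate 1 and Rarres2-/- replicate 4, a setting added after the data were seen, limma called 68 genes, 14 higher and 54 lower. Leaving out Rarres2-/- replicate 5 gave 1 gene, Rarres2, and leaving out Rarres2-/- replicate 6 gave 1 gene, the small nucleolar RNA gene Snord4a.

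Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, had a lower mean as a group in Rarres2-/-. The mean log2 difference over 17 tested members was -0.58, with 14 members lower and 3 higher (camera adjusted p = 5.79e-05; adjusted p = 0.936 with an estimated correlation). The median was smaller, at -0.27, as some members fell much further than others. Fry gave the list an adjusted p of 0.925. Counted by limma, 0 members passed over all genes and 3 (Ier2, Ier3 and Junb) passed adjusted over the list alone. Ier2 was at 24.1 ± 1.42 FPKM in WT and 9.69 ± 2.33 FPKM in Rarres2-/- (SD, n = 3 each), Ier3 at 13.2 ± 4.68 and 3.19 ± 1.44 FPKM, and Junb at 19.1 ± 6.60 and 6.54 ± 2.78 FPKM, each with lower values in all 3 Rarres2-/- libraries. Egr1 was at 11.3 ± 8.03 and 2.78 ± 1.35 FPKM, with overlapping libraries. The list's mean log2 value overlapped between genotypes, at 3.46 in WT replicate 1 and 3.62 in Rarres2-/- replicate 4, and its exact permutation p was 0.2 (two-sided, n = 3 each, smallest possible 0.1). Without WT replicate 1 and Rarres2-/- replicate 4 the mean difference was -0.94.

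Genes of lipid storage and breakdown had a higher mean as a group in Rarres2-/-. Of 18 tested members of the lipolysis and lipid droplet list, 15 were higher, with a mean log2 difference of 0.32 (camera adjusted p = 6.31e-05; adjusted p = 0.460 with an estimated correlation). With limma, 0 members passed over all genes and 1, Fitm2, passed adjusted over the list alone. Fitm2, which acts in lipid droplet formation, was at 40.9 ± 7.99 FPKM in WT and 76.4 ± 7.23 FPKM in Rarres2-/- (SD, n = 3 each). Prkar2b, a regulatory subunit of protein kinase A, was at 264 ± 49.0 and 429 ± 38.3 FPKM. The lipid droplet coat genes Plin1 (553 ± 42.7 and 789 ± 94.8 FPKM) and Plin2 (203 ± 29.4 and 285 ± 25.3 FPKM) were also higher in all 3 Rarres2-/- libraries. The list's mean log2 value lay between 6.90 and 7.04 in WT and between 7.22 and 7.35 in Rarres2-/- (exact permutation p = 0.1, two-sided, n = 3 each, the smallest possible). The classical brown fat list and the unfolded protein and heat shock response list, which camera did not call, reached the same exact permutation p. The lipolysis and lipid droplet list and the immediate early genes kept their calls at the preset correlation when any 1 library was left out. With an estimated correlation neither passed in those fits, with adjusted p of 0.488 to 0.959 for this list and 0.488 to 0.973 for the immediate early genes.

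Fat and sterol synthesis and mitochondrial fuel use also had higher means in Rarres2-/-. Of 23 lipogenesis genes, 21 were higher in Rarres2-/- (mean log2 difference 0.34, camera adjusted p = 0.000730, adjusted p = 0.936 with an estimated correlation). Gpam, which starts triglyceride synthesis, was at 18.3 ± 4.29 FPKM in WT and 34.8 ± 7.63 FPKM in Rarres2-/- (SD, n = 3 each), and the acetyl-CoA carboxylase genes Acaca and Acacb had log2 differences of 0.84 and 0.70. Fatty acid oxidation rose by a mean of 0.20, with 21 of 23 members higher (adjusted p = 0.00388, adjusted p = 0.936 with an estimated correlation), with Acsl1 at 604 ± 50.6 and 960 ± 109 FPKM and Acot2 at a log2 difference of 0.53. Cholesterol synthesis rose by a mean of 0.24, with 17 of 20 members higher (adjusted p = 0.00939, adjusted p = 0.936 with an estimated correlation). Hmgcs1, an early enzyme of that pathway, was at 32.5 ± 8.18 and 72.1 ± 16.8 FPKM. TCA cycle genes rose by a mean of 0.23, with 15 of 16 members higher (adjusted p = 0.0215, adjusted p = 0.936 with an estimated correlation). Ogdh had a log2 difference of 0.25 and Pdha1 one of 0.53, with Pdha1 lowest of all in Rarres2-/- replicate 4. With 1 library left out, Pdha1 ran from 0.27 to 1.03. The TCA cycle call was lost at the same mean when a gene needed 5 FPKM in 3 libraries (0.23, camera adjusted p = 0.0620). No member of these 4 lists passed over all genes or adjusted over the list alone. The mean log2 values of all 4 lists overlapped between genotypes, with exact permutation p (two-sided, n = 3 each) of 0.3 for lipogenesis, 0.4 for fatty acid oxidation and 0.5 for cholesterol synthesis and the TCA cycle. For the last 3 lists Rarres2-/- replicate 4 lay below every WT library. None of the 4 kept its call when each library was left out in turn. Without Rarres2-/- replicate 6 the means were 0.19 for lipogenesis (adjusted p = 0.0789), 0.09 for fatty acid oxidation (0.217), 0.11 for cholesterol synthesis (0.203) and 0.03 for the TCA cycle (0.798). Without WT replicate 3 they were 0.16 for lipogenesis (0.149), 0.14 for cholesterol synthesis (0.191) and 0.22 for the TCA cycle (0.10). Without Rarres2-/- replicate 5 they were 0.20 for lipogenesis (0.0460), 0.09 for cholesterol synthesis (0.266) and 0.10 for the TCA cycle (0.266), and without WT replicate 1 the mean was 0.18 for the TCA cycle (0.0820). Without Rarres2-/- replicate 4 the means were larger, at 0.64 for lipogenesis (3.35e-08), 0.38 for fatty acid oxidation (6.74e-08), 0.53 for cholesterol synthesis (1.81e-07) and 0.57 for the TCA cycle (1.89e-10). With an estimated correlation the adjusted p in that fit was 0.490 for each. In Rarres2-/- replicate 4 the lipogenesis, fatty acid oxidation, cholesterol synthesis and TCA cycle lists lay below the mean of all libraries, by median log2 deviations of -0.42, -0.36, -0.41 and -0.55.

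Thermogenic genes of brown and beige fat rose by a mean log2 difference of 0.20 (camera adjusted p = 0.0169; adjusted p = 0.936 with an estimated correlation). Of 24 tested members 16 were higher and 8 lower, and 0 passed over all genes or adjusted over the list alone. Ucp1, the uncoupling protein that produces heat, was at 43.1, 46.6 and 56.1 FPKM in WT and 61.5, 62.8 and 74.6 FPKM in Rarres2-/-, a log2 difference of 0.44 (SE 0.170). The proton channel gene Otop1 was at 5.87 ± 0.620 FPKM in WT and 10.9 ± 3.16 FPKM in Rarres2-/- (SD, n = 3 each), the glycerol kinase gene Gyk at 2.83 ± 0.629 and 5.11 ± 1.72 FPKM, and Ckmt2, which muscle also expresses, had a log2 difference of 1.17. The list's mean log2 value overlapped between genotypes (exact permutation p = 0.2, two-sided, n = 3 each). The call was lost without WT replicate 2 (mean 0.14, adjusted p = 0.15), WT replicate 3 (0.15, 0.111) or Rarres2-/- replicate 6 (0.15, 0.146), and the mean was 0.31 without WT replicate 1 (0.000743). The call was also lost at a similar mean without Rarres2-/- replicate 4 (0.19, 0.0923) and with array weights (0.21, 0.118), and when a gene needed 5 FPKM in 3 libraries (0.532, mean 0.06 over 16 members).

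**Figure D2:**
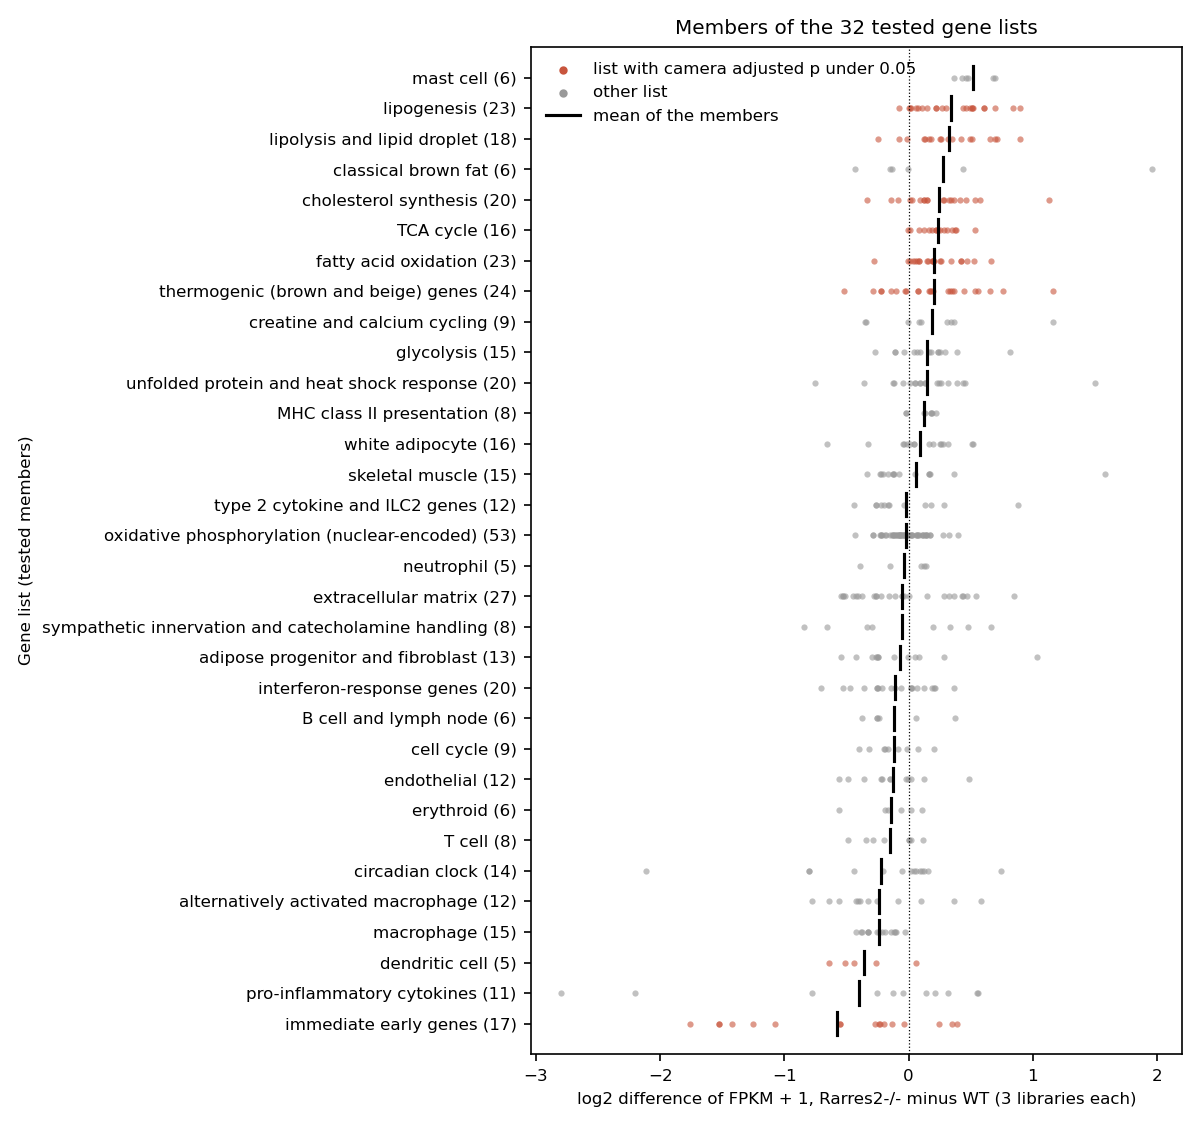
Log2 differences of FPKM + 1 (Rarres2-/- minus WT, 3 libraries each) of the members of 32 gene lists, 1 point per gene, with the mean of each list as a black bar and the 8 lists with a camera adjusted p under 0.05 in red. Means run from -0.58 for immediate early genes to 0.52 for mast cell genes, and most members of the lipid lists lie to the right of 0.

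Among immune and stromal cell markers, dendritic cell genes fell by a mean log2 difference of 0.36 in Rarres2-/-, with 4 of 5 tested members lower (camera adjusted p = 0.0213; adjusted p = 0.936 with an estimated correlation; 0 members over all genes or adjusted over the list alone). Batf3 was at 4.48 ± 0.575 FPKM in WT and 2.86 ± 0.596 FPKM in Rarres2-/-, and Irf8 at 7.37 ± 0.544 and 5.23 ± 1.10 FPKM (SD, n = 3 each). Those values were lower in all 3 Rarres2-/- libraries. The list's mean log2 value overlapped between genotypes (exact permutation p = 0.2, two-sided, n = 3 each). Its mean difference was -0.26 without WT replicate 3 (adjusted p = 0.131), -0.33 without Rarres2-/- replicate 5 (0.0696) and -0.27 without Rarres2-/- replicate 6 (0.199). It was -0.20 without a filter (0.0541). The call was also lost at a similar mean with scaling that left out the 20 most abundant genes (-0.35, 0.0767) and with length trends removed (-0.33, 0.0810). All 15 macrophage genes had lower means in Rarres2-/- (mean log2 difference -0.24, adjusted p = 0.139), among them Aif1 at -0.38. With 1 library left out, Aif1 ran from -0.72 to -0.10 and the mean of the list from -0.78 to 0.04. Alternatively activated macrophage genes had a mean of -0.24 (adjusted p = 0.499), with Cd209f at -0.78, which was -1.71 without WT replicate 1, -0.35 without WT replicate 2 and -0.28 without WT replicate 3. The type 2 cytokine and ILC2 list, with a mean of -0.02 over 12 members, had an adjusted p of 0.770. In it Il33 was at 4.79 ± 3.63 and 7.70 ± 1.98 FPKM and its receptor gene Il1rl1 at 1.06 ± 0.511 and 1.46 ± 0.113 FPKM, with overlapping libraries. WT replicate 1 lay far below the other libraries in macrophage genes (median log2 deviation -0.97). Without it the macrophage list had a mean of -0.78 and an adjusted p of 1.65e-11, alternatively activated macrophage genes -0.89 and 3.19e-09, and type 2 genes -0.27 and 0.0159. Without Rarres2-/- replicate 4 the macrophage list had a mean of -0.35 and an adjusted p of 0.0382. These calls rest on the preset correlation. With an estimated correlation in the same fits the adjusted p was 0.488 for both macrophage lists and 0.552 for type 2 genes without WT replicate 1, and 0.812 for the macrophage list without Rarres2-/- replicate 4. Over all fits with 1 library left out, means ran from -0.89 to 0.14 for alternatively activated macrophage genes and from -0.27 to 0.13 for type 2 genes. Neither these lists nor the macrophage list kept a direction in all of those fits.

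The pro-inflammatory cytokine list had a mean of -0.40 (camera adjusted p = 0.548) and a median of -0.05, with 5 members higher and 6 lower. Its mean rests largely on log2 differences of -2.80 for Ccl7 and -2.20 for Ccl2. The chemokine genes Ccl7 and Ccl2 were at 37.1 and 29.3 FPKM or more in WT replicates 2 and 3, at 3.57 and 2.11 FPKM in WT replicate 1, and at 1.30 to 4.03 and 1.59 to 6.08 FPKM in Rarres2-/-. Socs3 had a log2 difference of -0.78 and Tnfaip3 of 0.55. Interferon-response genes had a mean of -0.11 (adjusted p = 0.316), with Cmpk2 at -0.53, and -0.28 (0.000196) without WT replicate 1. The other cell type lists had adjusted p of 0.139 for mast cells (mean 0.52), 0.254 for white adipocytes (0.09), 0.548 for endothelial cells (-0.13), 0.548 for T cells (-0.15), 0.730 for B cells and lymph node (-0.12), 0.605 for progenitors and fibroblasts (-0.07), 0.548 for erythroid cells (-0.14), 0.897 for neutrophils (-0.04), 0.707 for skeletal muscle (0.06) and 0.548 for classical brown fat (0.28). With 1 library left out, means ran from -0.54 to 0.43 for B cells and lymph node and from -0.63 to 0.24 for progenitors. They ran from -0.33 to 0.08 for erythroid cells and from -0.45 to 0.87 for skeletal muscle. Single members went further than their lists. Cd36 had a log2 difference of 0.52, Cfd -0.66, F3 1.03, Lum -0.54, Tek -0.49, Lhx8 0.44, and Pdk4, at 17.0 to 59.1 FPKM in WT and 68.9 to 216 FPKM in Rarres2-/-, 1.96. Without WT replicate 1 the endothelial list was higher in Rarres2-/- (0.62, adjusted p = 0.00915), the mast cell list lower (-0.30, 0.0284), skeletal muscle higher (0.87, 1.63e-10) and progenitors lower (-0.63, 4.26e-07). Without WT replicate 3 the endothelial list was lower (-0.53, 0.0482), and without Rarres2-/- replicate 4 it was too (-0.67, 0.0149). The mast cell list was higher without WT replicate 2 (0.98, 0.0131) or WT replicate 3 (0.87, 0.0382). T cell genes were lower without WT replicate 2 (-0.58, 0.000320) and higher without WT replicate 3 (0.40, 0.00554), and white adipocyte genes were higher without Rarres2-/- replicate 4 (0.24, 0.00708). All of these calls with a library left out rest on the preset correlation, and their adjusted p ran from 0.488 to 0.953 with an estimated correlation in the same fits. Myh1 was the 1 skeletal muscle gene that passed adjusted over the list alone.

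Nuclear-encoded oxidative phosphorylation genes had a mean of -0.02 over 53 members, with 22 higher and 31 lower (adjusted p = 0.811). Sdha had a log2 difference of 0.32. In Rarres2-/- replicate 4 the list lay at a median log2 deviation of -0.81, and without that library the mean was 0.37, higher in Rarres2-/- (adjusted p = 2.16e-12), while without Rarres2-/- replicate 6 it was -0.29 (0.00116). With an estimated correlation in these fits the adjusted p was 0.490 and 0.995. The remaining lists had adjusted p of 0.0972 for the unfolded protein and heat shock response (mean 0.15, with Chac1 at 2.73 FPKM in WT and 10.5 FPKM in Rarres2-/- and Ddit3 at a log2 difference of -0.76), 0.316 for the cell cycle (-0.12, Ccna2 -0.40), 0.368 for glycolysis (0.15), 0.499 for the circadian clock (-0.22, Per1 0.75), 0.548 for creatine and calcium cycling (0.19, Ckb -0.35), 0.548 for MHC class II presentation (0.12), 0.548 for sympathetic innervation (-0.06, Slc22a3 0.66 and Nrg4 0.47) and 0.703 for extracellular matrix (-0.05, Col15a1 0.43). The median had the opposite sign to the mean for the circadian clock (0.03), skeletal muscle (-0.12), classical brown fat (-0.07) and neutrophils (0.10), and the test for sympathetic innervation pointed up against a mean and a median (-0.05) below 0. Glycolysis passed without Rarres2-/- replicate 4 (0.41, adjusted p = 0.000378), extracellular matrix without WT replicate 1 (-0.38, 2.26e-05), and the unfolded protein list without WT replicate 2 (0.19, 0.0400). MHC class II (0.42, 0.00938) and the circadian clock (-0.39, 0.0228) passed without WT replicate 3, and the cell cycle without a filter (-0.15, 0.000289). With an estimated correlation the adjusted p of these lists with a library left out ran from 0.490 to 0.906. Bhlhe40 was the 1 clock gene that passed adjusted over the list alone.

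The main differences between libraries did not follow genotype. The mean Pearson correlation over genes, which are not independent replicates, was 0.952 between libraries of the same genotype and 0.954 between genotypes. The first value minus the second was -0.00220, and 0.00117, 0.00123 and 0.00297 without WT replicate 1, 2 or 3. It was -0.00634, -0.00858 and -0.00364 without Rarres2-/- replicate 4, 5 or 6, and -0.0133 over the 500 most variable genes. The first principal component held 43.1% of the variance and set WT replicate 1 apart, and the second held 26.7% and set Rarres2-/- replicate 4 apart. The third held 16.7% and parted the genotypes, with scores of -22.1 to -6.09 in WT and 9.81 to 25.3 in Rarres2-/-. WT replicate 1 was high in endothelial (median log2 deviation 1.75) and skeletal muscle genes (1.70) and low in progenitor (-1.06) and mast cell genes (-2.61). Rarres2-/- replicate 4 was also high in endothelial genes (1.24). WT replicate 3 was high in T cell (1.10) and B cell genes (1.02).

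**Figure D3:**
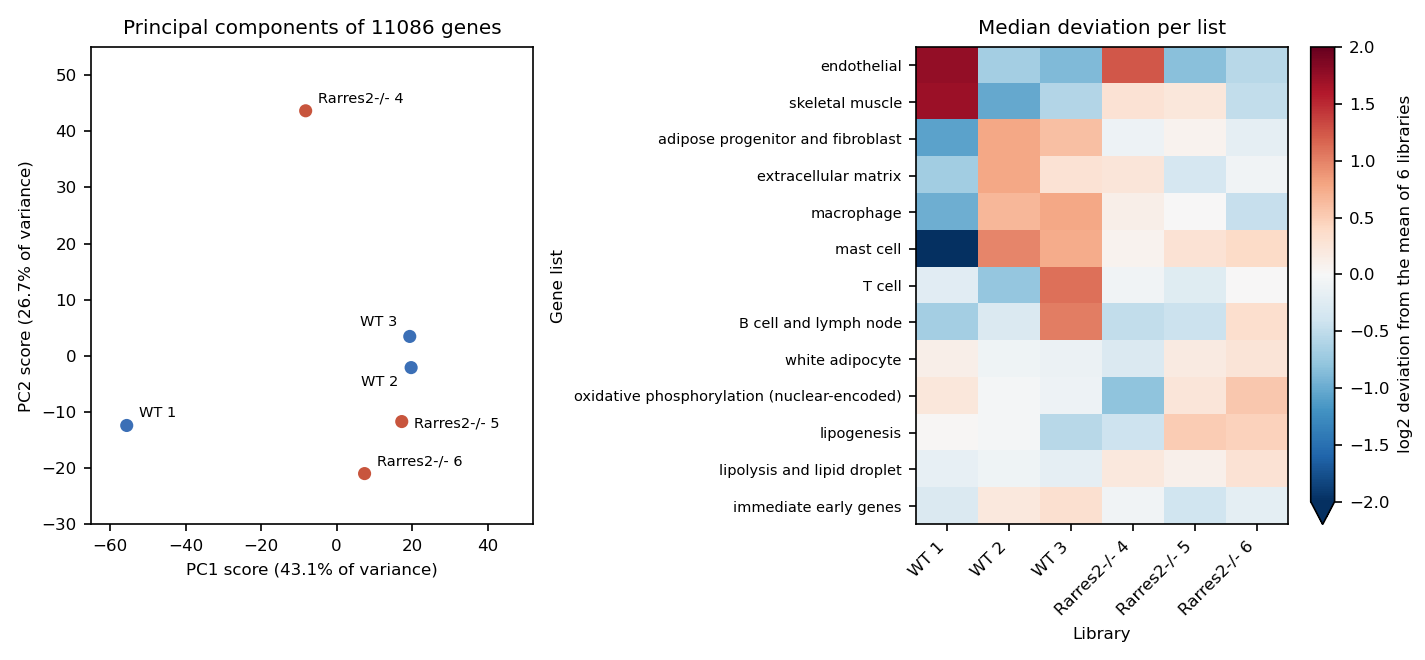
Left, scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over 11086 genes, WT in blue and Rarres2-/- in red; right, median log2 deviation of the members of 13 gene lists from the mean of the 6 libraries, 1 column per library, with colours limited to -2 to 2. WT replicate 1 and Rarres2-/- replicate 4 lie apart and share high endothelial values of 1.75 and 1.24.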

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

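Rows without a gene symbol, which no comparison used, had a higher summed FPKM in Rarres2-/- than in WT. The sum was 20421 ± 4751 in Rarres2-/- and 14767 ± 265 in WT (SD, n = 3 each). All 3 Rarres2-/- libraries lay above all 3 WT libraries (exact permutation p = 0.1, two-sided, the smallest possible). Rarres2-/- replicate 4 had the highest value, 25857, and the others were 17060 and 18347. As a share of summed FPKM the genotypes overlapped, at 0.793%, 2.22% and 2.30% in WT and 4.91%, 2.06% and 2.40% in Rarres2-/-. No explanation was tested.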

How the results depend on the processing

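Leaving out both outlying libraries (WT replicate 1 and Rarres2-/- replicate 4), an estimated correlation with libraries left out, and removing length or GC trends were chosen after seeing the data. No paired analysis was possible because no sample number occurs in both genotypes. The robust fit was not run for list tests. The count of genes past the threshold, 0, was also 0 with quantile normalization, no filter, no trend, a pseudocount of 0.1, robust empirical Bayes and either trend removed. Also requiring an absolute log2 difference of at least 1 can only lower the count, so it stayed at 0 by construction. It was 1, Rarres2, at an adjusted p of 0.1, with upper-quartile scaling, with scaling without the 20 most abundant genes and with 5 FPKM in 3 libraries, which tests fewer genes. The count ran from 0 to 1 over the fits with 1 library left out, and was 68 without both outlying libraries and 1524 with array weights, whose estimation gave a convergence warning. Of the 68 genes, 65 were among the 1524. Array weights gave the outlying libraries weights of only 0.192 and 0.179, so both fits draw on much the same libraries and the overlap is no separate support. The log2 difference of Rarres2 ran from -8.40 (pseudocount 0.1) to -6.47, and its adjusted p from 0.00198 to 0.469. It passed with upper-quartile scaling (-7.54), without the 20 most abundant genes (-7.55), with 5 FPKM in 3 libraries (-7.51), with array weights (-6.47) and without both outlying libraries (-7.04), and ran from -8.20 to -6.93 with 1 library left out. The mean correlation within minus between genotypes moved by less than the SD of the correlations within genotypes (0.0267) in all 7 alternatives. That limit is wide next to the value itself (-0.00220), whose sign changed without WT replicate 1, 2 or 3.

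The 8 lists became 5 with 5 FPKM in 3 libraries, 16 with array weights, 20 without both outlying libraries (10 higher, 10 lower), 0 with an estimated correlation without both or without any 1 library, and 0 with an estimated correlation or fry, and ran from 3 (without Rarres2-/- replicate 6) to 16 (without WT replicate 1) with 1 library left out. Without Rarres2-/- replicate 5 there were 5. Fry, which asks whether a list moves on balance, gave its smallest adjusted p, 0.130, for the lipolysis and lipid droplet list. Over fits with 1 library left out, means ran from -0.67 to 0.62 for endothelial, -0.30 to 0.98 for mast cell, -0.58 to 0.40 for T cell and -0.29 to 0.37 for oxidative phosphorylation genes, and log2 differences from -0.80 to 0.38 for Gpr1 and -0.060 to 0.29 for Ccrl2. Gpr1 was at 0.031 with a pseudocount of 0.1. Oxidative phosphorylation changed to 0.32 with array weights and 0.46 without both outlying libraries, where mast cell genes were at -0.27 and MHC class II genes at -0.39. The cause of these changes was not tested. The alternatives followed 71 named genes, Rarres2 included. Those other than Rarres2 gave 1247 values, of which 1181 kept their direction and side of the threshold, 60 passed it and 6 changed sign. Of those 60, 50 passed with array weights and 10 without both outlying libraries. Many of these genes were chosen for separated groups, whose direction cannot change when a library is left out, and none passed in the main fit. The 1181 are therefore no measure of how firm the differences are. List means gave 824 values, of which 684 kept their side, 95 lost a call, 37 gained it and 8 changed sign with a call. Of the 684, 86 had no call and changed sign. Lower depth in WT replicate 1 limits the precision of low genes in that library.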

Other observations

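The fit without both outlying libraries, with either correlation, and the trend removals were chosen after seeing the data, the test of attached muscle was written after the values it uses were seen, and the gene lists for hormone signals were chosen after single genes had been seen.

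Without WT replicate 1 and Rarres2-/- replicate 4, which leaves 2 libraries of each genotype, macrophage, progenitor and matrix lists had lower means in Rarres2-/-. WT replicate 1 had been seen to be low in these lists (median log2 deviations of -0.97 for macrophage, -1.28 for alternatively activated macrophage, -1.06 for progenitor and -0.70 for matrix genes), so leaving it out by itself lowers Rarres2-/- relative to WT. Mean log2 differences were -0.89 for macrophage genes (camera adjusted p = 1.19e-10), -0.91 for alternatively activated macrophage genes (5.82e-07), -0.65 for progenitor genes (4.06e-07), -0.56 for extracellular matrix (1.55e-06) and -0.29 for interferon-response genes (0.00134). White adipocyte genes were higher by 0.30 (0.00952), glycolysis by 0.44 (0.000667) and skeletal muscle by 0.76 (7.05e-05). These calls rest on the preset correlation. Each of these lists had an adjusted p of 0.480 with an estimated correlation in the same fit, where 0 lists passed. Among named genes, Ccl7 and Ccl2 then had log2 differences of -4.27 and -3.90, Cd209f -1.85, Lum -1.08, Junb -1.88, Ier2 -1.46 and Ddit4 2.25, each past an adjusted p of 0.05. In the unweighted fit of all 6 libraries none of these genes or lists passed. With array weights all of them did, but those give both libraries little weight, so that is no separate support. Over the alternatives the highest adjusted p was 0.995 for the macrophage, progenitor and skeletal muscle lists.

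The lists of T cell and B cell genes had their highest medians in WT replicate 3, shown here by genes chosen after their values were seen. There Tcf7, a T cell transcription factor gene, was at 5.29 FPKM and Cd79b, a B cell receptor gene, at 6.75 FPKM, while the other WT libraries had at most 0.595 and 0.940 FPKM. Rarres2-/- libraries held 0.282 to 0.955 FPKM of Tcf7 and 0.804 to 4.01 FPKM of Cd79b. Eosinophil and NK cell lists had too few members above 1 FPKM to be tested. The eosinophil-attracting chemokine gene Ccl24 was at 3.73, 23.2 and 29.4 FPKM in WT and 8.79, 6.76 and 7.42 FPKM in Rarres2-/-. Snord2 reached 1.17e+06 FPKM in WT replicate 1, and Mir1935 held 16.7% of summed FPKM in Rarres2-/- replicate 5.

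A glucocorticoid signal is a candidate explanation for the higher Ddit4, Tsc22d3, Irs2 and Arrdc3 in Rarres2-/-, since these genes respond to that hormone or to fasting. Of 15 other glucocorticoid-induced genes, listed before their values were seen, 14 were tested. Their mean log2 difference was 0.46, with 10 higher and 4 lower, and their mean was higher in each Rarres2-/- library than in any WT library. That separation was narrow, with mean log2 values of 5.54 in WT replicate 1 and 5.58 in Rarres2-/- replicate 6. The camera p was 0.000307 with the preset correlation and 0.0530 with an estimated correlation, so the result rests on the preset value. Cebpd had a log2 difference of 1.26, Errfi1 1.47, Gadd45g 0.91 and Angptl4 1.21, while Fkbp5 (0.24), Klf9 (-0.15) and Zbtb16 (-0.66), also well-known targets, did not share a direction. With 1 library left out, Cebpd ran from 0.89 to 1.66, Errfi1 from 0.93 to 1.99, Gadd45g from 0.57 to 1.15 and Angptl4 from 0.67 to 1.61. These are members that rose, and the list as a whole was not refitted with 1 library left out. Genes of FOXO activity and low insulin (16) had a mean of 0.086, with 11 higher and 5 lower, which neither shows nor excludes that signal. Handling stress, time of day and feeding, which act on the same genes, were not tested.

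WT replicate 1 stood apart from all other libraries. Lower depth argues poorly for it, because among 834 genes with at least 100 FPKM, where counting noise is small, its median absolute log2 difference from the other WT libraries was 2.91 times that between them. Removing length trends left 0.986 of its distance from them. Its deviations followed GC content (Spearman rho 0.281 over genes, which are not independent), against -0.309 to 0.0816 in the other libraries. Removing GC trends was not tried for this distance, so a GC bias stays open. Attached muscle alone would dilute other cell types alike, but the progenitor list lay at -1.57 and the white adipocyte list at 0.16 against the other WT libraries, a gap of -1.73. A different piece of the depot, with more vessels and muscle and less stroma, stays open, and apart from attached muscle alone no biological explanation was tested.

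In Rarres2-/- replicate 4, oxidative phosphorylation genes had a median log2 deviation of -1.23 from the other Rarres2-/- libraries. A smaller adipocyte share is argued against, since white adipocyte genes lay at -0.33, a gap of 0.90. A length bias may hold part of it. The deviations of this library followed transcript length (Spearman rho 0.416 over genes, which are not independent). Those of Rarres2-/- replicate 6, which is part of the reference here, followed length in the other direction (-0.351). The list's median transcript is 1232 bases against 3313 for all tested genes. Removing length trends left a deviation of -0.82, or 0.664 of the original. That value lies between the bounds set in advance for and against length, so its share cannot be told apart from other causes, and apart from the adipocyte share no biological explanation was tested.

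Immediate early genes were lower in Rarres2-/- by a mean of -0.58. Removing length trends left 0.975 and removing GC trends left 0.939 of that difference, which argues against either bias as its source. The time between death and freezing cannot be told apart from genotype, because these genes respond to handling, no label gives the time, and the list's mean ranged over 0.73 within WT and 0.58 within Rarres2-/-, as wide as the difference between genotypes. An effect of genotype stays open and was not tested apart from handling.

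With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For genes past the threshold the real split gave 0 and the highest other 1. All 10 of the 10 splits gave as many, which a real count of 0 makes certain, so that comparison decides nothing. At an unadjusted p under 0.05 the real split gave 436 and the highest other 1306, with 6 splits as large. That highest split, WT replicate 1 with Rarres2-/- replicates 5 and 6 against the rest, points to a structure of the samples other than genotype. For gene lists the real split gave 8 and the highest other 17, with 10 of the 10 splits as large. Every split that mixed the genotypes thus gave at least as many list calls at the preset correlation. The count of 8 is therefore no sign of an effect of genotype.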
